A study of Homo sapiens with 8 samples.

How the data were processed

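Total RNA of 4 wild-type and 4 radiation-resistant HL60 samples was extracted with an ISOGEN kit, labelled with Cy3 from 100 ng and hybridised to Agilent human miRNA arrays, per the labels' protocols. Samples were grouped by their titles. The same irradiation text stands on all samples in the labels, so a dose of the wild-type samples is not stated and the wild type is taken as unirradiated from the series design only.

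The arrays were scanned in 1 colour and read with Agilent Feature Extraction 11.5.1.1, with 1 scan date and 1 slide shared by all arrays, per the file headers. The deposited intensity values per spot are linear, background-subtracted and spatially detrended by that software and not normalized between arrays, per the file headers. The intensity columns used were the processed signal, the software's total gene signal, and the median raw and background signals. The flags for detection, saturation, outliers and signal well above background were used as deposited. The authors' value table holds linear intensity values for 2629 of the 3523 probes. How it was made is not given in the sources used here. Set against each array's spots, its columns ranked as the mean of the spots that were positive and significant (Spearman correlation from 0.992 to 1.000 across probes), and a value was missing where a probe had no such spot, with at most 1 exception per array. Its column medians were 4.07, 4.15, 5.02 and 3.99 on the wild-type and 3.46, 4.42, 3.76 and 4.59 on the resistant arrays. Its column maxima were 24351, 20687, 24351 and 24351 on the wild-type and 24351, 24351, 24351 and 24523 on the resistant arrays. The repeated maximum speaks for a matching of the columns between arrays, but the method of any centring or normalization stays unstated. The scale is linear from the values, and higher values stand for brighter probes.

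Each array had 53880 miRNA spots. Control spots were left out, as were spots with an outlier flag, from 3.96% to 4.38% of the miRNA spots. Between 6.34% and 9.62% of the spots were well above background, between 40.0% and 48.2% lay at or below 0, and 0 were saturated. Spots of one probe were averaged and the probes of one miRNA were summed on the linear scale. Each array was divided by its 75th percentile over the 137 miRNAs detected on all arrays. A floor was then set at the 5th percentile of the scaled signals of detected miRNAs, 0.0431, and log2 was taken. Names are those of the array design, some of which carry an older database version that is left off in the text. No coordinates are given, because the grid of the arrays uses hg19 and the annotation at hand GRCh38.p14. The latter served only to find neighbouring miRNA genes, with 147 of the 154 tested human miRNAs matched.

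MiRNAs detected on at least 3 of the 4 arrays of at least 1 group were tested, 163 in all, with limma 3.58.1 (lmFit and eBayes, groups as the only term) in R 4.3.3 and Benjamini-Hochberg adjustment. Calls have an adjusted p under 0.05. A miRNA detected on all 4 arrays of one group and 0 of the other has only a bound, the mean of the bright group against, per array, the higher of the dim signal and the lowest signal of a detected miRNA. Lists of miRNAs, 23 in all, were tested where at least 3 members were tested, with camera at a preset correlation of 0.01, camera with an estimated correlation, and fry. A list count adjusted over the list alone used the same fit. Values with 1 number per array were compared by an exact two-sided permutation test over 70 assignments. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the figures.

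The named miRNAs follow a rule. It takes up to 10 rises and up to 10 falls with the largest log2 change among calls that were detected on all arrays and did not overlap between groups, up to 4 per direction detected in 1 group alone, up to 4 tested members of each list with the highest mean signal, and a fixed set of miRNAs of myeloid or radiation interest. The lists, the rule, the tests of miRNAs and of lists and the alternatives were fixed before the data were examined, apart from 4 alternatives. These, and the tests of explanations chosen later, are named where they are given. The comparisons of spike-in signals were added after the data were seen.

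The tests of miRNAs and of lists, but not the scaling, floor, probe summary or filter, were tried on simulated log2 values. These had independent normal noise around the mean of each miRNA. In 50 simulations of the 163 miRNAs, 20 were changed by 1.5-fold and 20 by 2-fold, as many up as down. Of these, 87.1% and 97.4% were recovered, and 4.42% of the calls were false. Without a change there were 0.06 calls per simulation. The myeloid list, with 13 tested members, was recovered in 100% of the simulations when shifted by 0.5 on the log2 scale. Without a change, 6% of the simulations called a list. Members of a list were simulated as uncorrelated, while the correlations estimated within the tested lists ran from 0.10 to 0.85. These rates may therefore not hold for the data. The alternatives covered the scaling, the background correction, the summary of probes, the source of the values, the filter, the floor, the variance model, the replicate number and the slide row as a block, each row alone, and each replicate left out. Normexp was run on the median spot and background signals, since a mean spot signal was not among the columns at hand.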

Results

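MicroRNAs (miRNAs), short RNAs that lower the output of their target mRNAs, were measured in HL60 cells. These are a human line of acute myeloid leukaemia that is widely used as a model of myeloid cells and lacks functional p53. The question was which miRNAs differ between the wild-type line and a radiation-resistant line derived from it by repeated X-irradiation. The irradiation was 4 Gy in each of 4 fractions within 4 weeks, 16 Gy in total, followed by at least 7 days in culture medium. There were 4 wild-type and 4 resistant samples, and 1 array was made from 100 ng of total RNA of each. The labels do not say whether the 4 samples of a group came from separate cultures, so the p-values measure the spread between these arrays, which may be technical. Each array held probes for 1347 miRNAs, 1205 human and 142 viral. The wild-type arrays detected 172, 167, 139 and 179 of them, and the resistant arrays 199, 157, 192 and 152. In all, 137 were detected on every array and 1134 on none, and 163 were tested. The number of arrays limits the precision: the median residual standard deviation was 0.18 on the log2 scale. All arrays lay on 1 slide, with the wild-type arrays in columns 1 and 2 and the resistant arrays in columns 3 and 4, so group and slide column cannot be told apart. Levels below are log2 signals relative to the 75th percentile of the array, as mean ± SD with n = 4.

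Apart from miRNAs whose wild-type values all lay at the floor, such as miR-146a-5p, the largest fitted changes between resistant and wild-type cells were in miR-324-5p and miR-1246. MiR-1246, an entry matching a fragment of the U2 small nuclear RNA that has been described as induced by p53, was 3.10 ± 0.20 in resistant cells and 1.93 ± 0.16 in wild-type cells, which was 2.25-fold higher (log2 change 1.17, SE 0.13, adjusted p = 4.74e-05). MiR-124-3p, best known from neurons, rose 1.73-fold, from -1.37 ± 0.22 to -0.58 ± 0.05 (adjusted p = 0.000932). Let-7e-5p, of the let-7 tumour suppressor family, rose 1.64-fold (log2 change 0.71, SE 0.17, adjusted p = 0.0140). MiR-128-3p rose 1.54-fold (adjusted p = 0.00721), and miR-590-5p 1.43-fold (adjusted p = 0.0140). All of these had 4 resistant values above all 4 wild-type values. Apart from miR-324-5p, the rule that named them required this, so it is no further support.

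**Figure D1:**
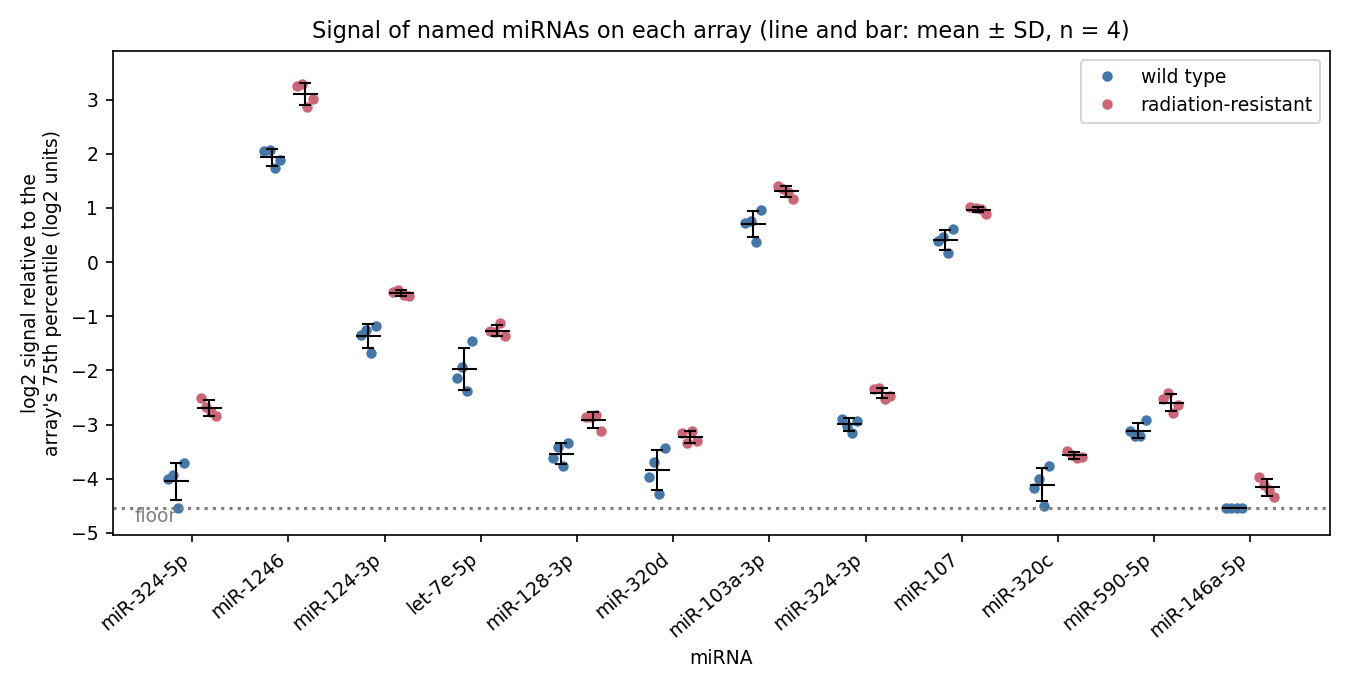
Log2 signal of 12 miRNAs relative to the 75th percentile of the array (y axis, log2 units), with 1 point per array, for wild-type (blue) and radiation-resistant cells (red), and the mean ± SD of 4 arrays in black. In each miRNA shown, the 4 resistant arrays lie above the 4 wild-type arrays. The dotted line is the floor, on which all wild-type values of miR-146a-5p lie.

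Both arms of the miR-324 hairpin rose. MiR-324-3p rose 1.49-fold (log2 change 0.58, SE 0.11, adjusted p = 0.00485). Its probes were of like brightness but differed in their change, at 0.83 (SE 0.07) and 0.29 (SE 0.10), so its size is uncertain. MiR-324-5p rose 2.56-fold, from -4.05 ± 0.35 to -2.70 ± 0.15 (adjusted p = 4.74e-05). It was detected on 3 of the 4 wild-type arrays and therefore lies outside the rule for named miRNAs, and it is named here after its values were seen. MiR-103a-3p and miR-107, nearly identical miRNAs whose genes lie in pantothenate kinase genes, rose 1.52-fold and 1.47-fold (adjusted p = 0.00934 and 0.00785). MiR-320c and miR-320d rose 1.45-fold and 1.53-fold (adjusted p = 0.0207 and 0.0193), and the related miR-320a, miR-320b and miR-320e, outside the rule because they were detected on 3 wild-type arrays, rose by 0.51, 0.57 and 0.59 on the log2 scale. Within the pair of miR-103a and miR-107 and the miR-320 family the sequences are so alike that probes may bind several members, so their separate values are uncertain.

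In all, 25 of the 163 tested miRNAs passed limma's test at an adjusted p under 0.05, and all 25 were higher in resistant cells. At an unadjusted p under 0.05 there were 59. Only miR-1246 and miR-324-5p had a fitted change of 2-fold or more, and the fitted changes of miRNAs with values at the floor, such as miR-146a-5p, are understated. The 4 resistant values did not overlap the 4 wild-type values in 37 miRNAs (22.7%, where chance gives 2.86%), among them 22 of the 25. The called miRNAs chosen after their values were seen also include miR-362-5p, miR-26b-5p, miR-3665 and miR-99a-5p, which rose by 0.44, 0.41, 0.40 and 0.40 on the log2 scale. The direction of the calls depended on the scaling. Over all tested miRNAs the median change was 0.16 (1.12-fold), and relative to it miR-1246 changed by 1.01, miR-124-3p by 0.63, let-7e-5p by 0.55 and miR-103a-3p by 0.44. When the arrays were scaled by their median in place of the 75th percentile, 13 miRNAs were higher and 17 lower. The split was 6 higher and 4 lower after quantile normalization, 6 and 9 with the authors' value table, 8 and 6 after centring on the median of the tested miRNAs, 1 and 2 with the percentile over all miRNAs, and 4 and 0 with spike-ins. Only 5 of the 25 were called as higher under all of the median, the quantile, the value table and the centring. They were miR-1246, miR-324-5p, miR-124-3p, miR-103a-3p and miR-107. With the percentile over all miRNAs only miR-1246 of these 5 was called, with spike-ins miR-103a-3p and miR-107 were not (adjusted p = 0.0762 each), and without scaling none was. The lower calls under the median, the quantile, the value table and the centring included miR-425-5p, miR-342-3p and miR-23b-3p, chosen after their values were seen. MiR-425-5p changed by -0.35 (adjusted p = 0.0576) as scaled here and by -0.55 (adjusted p = 0.00179) under the median. Its adjusted p ran from 0.00179 to 0.965 over the value table and the other scalings. Under spike-in scaling its log2 change was 0.02 (adjusted p = 0.962), which was no call. Leaving out wild-type replicate 1 gave 8 calls and wild-type replicate 4 gave 41, and leaving out resistant replicates 1, 2 or 3 gave 4, 4 and 41. With the row of the slide as a block there were 25 calls. The 2 wild-type and 2 resistant arrays of row 1 gave 31 calls and those of row 2 gave 0 with limma, against 60 and 6 at an unadjusted p under 0.05.

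**Figure D2:**
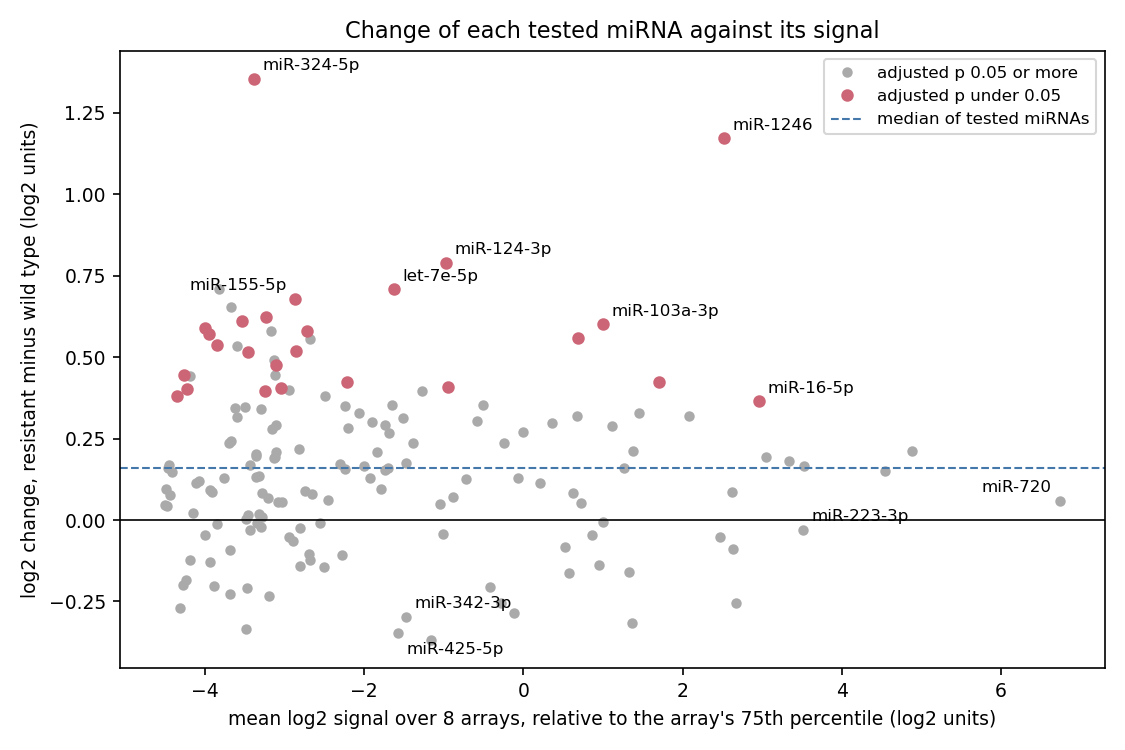
Log2 change, resistant minus wild type (y axis), against the mean log2 signal over 8 arrays relative to the 75th percentile of the array (x axis), with 1 point for each of the 163 tested miRNAs. Red points are the 25 miRNAs with an adjusted p under 0.05, all of them above 0, and the dashed line is the median change of 0.16. With the median, quantile normalization, the value table, centring and the percentile over all miRNAs, part of the calls lay below 0.

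**Figure D3:**
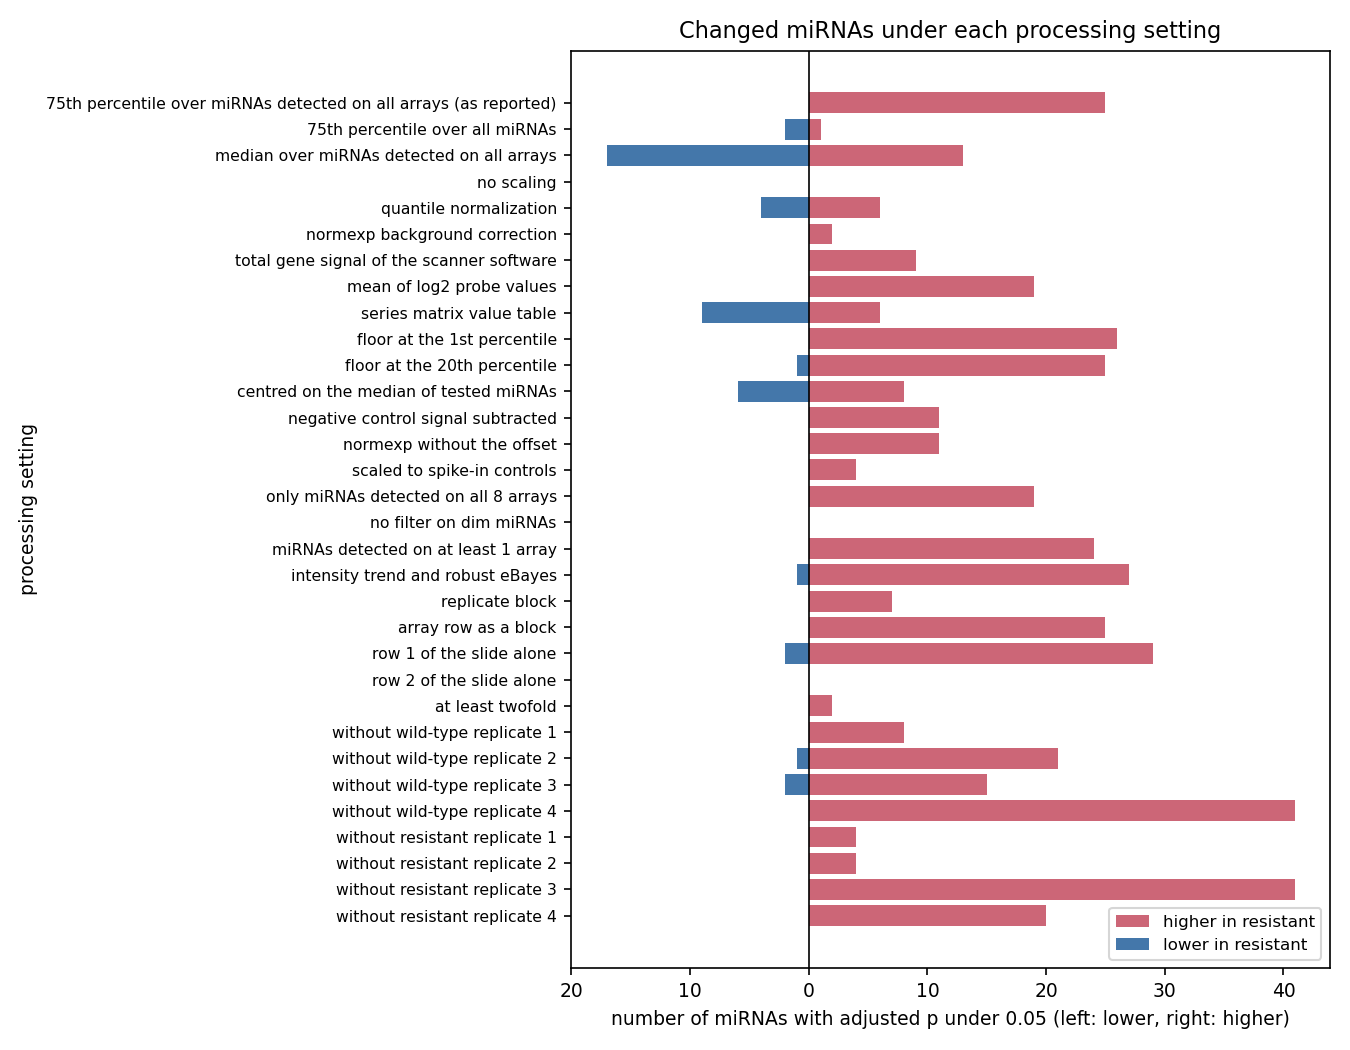
Number of miRNAs with an adjusted p under 0.05 (x axis) under each processing setting (y axis), with those higher in resistant cells to the right and those lower to the left. As scaled in the top bar there are 25 higher and 0 lower, and with the median over detected miRNAs there are 13 higher and 17 lower.

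MiR-146a-5p, an inducible regulator of NF-kB signalling in myeloid cells, was detected on all 4 resistant arrays and on none of the wild-type arrays. It was at least 1.83-fold higher in resistant cells, taking the lowest signal of a detected miRNA as the limit on each wild-type array. In the fit, with the wild-type values at the floor, the log2 change was 0.38 (SE 0.11, adjusted p = 0.0311). It was the 1 miRNA detected on all arrays of one group and none of the other. MiR-155-5p, a product of activated lymphoid and myeloid cells, rose 1.60-fold, from -3.21 ± 0.40 to -2.53 ± 0.11 (adjusted p = 0.0166), with overlapping values of the 2 groups. MiR-34a-5p, the best known target of p53 among miRNAs, and the hypoxia-induced miR-210-3p were detected on 0 arrays, and miR-125b-5p was detected on 4 of the 8 and not tested.

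Members of the myeloid list were called about as often as the tested miRNAs as a whole, of which 25 of 163 were called. Of 13 tested members of the myeloid list, 2 rose and 0 fell, or 5 and 0 adjusted over the list alone. MiR-23a-3p rose by 0.42 (SE 0.11) and miR-146a-5p was the other. MiR-223-3p, a leading miRNA of granulocytes, had a change of -0.03 (SE 0.11), miR-142-3p of -0.14, miR-142-5p of 0.16, miR-27a-3p of 0.33 and miR-21-5p of 0.40 (adjusted p = 0.0534). Among miRNAs that respond to retinoic acid in promyelocytic leukaemia cells, 2 of 13 rose, miR-107 and miR-16-5p, and 0 fell, with the same counts adjusted over the list alone. Their values were 0.56 and 0.37, beside 0.32 for miR-15b-5p and -0.09 for let-7a-5p, which did not pass. MiR-342-3p of this list, chosen after its values were seen, had -0.30 and was not called as scaled here. It was called as lower under the median, the quantile, the value table and the centring. MiR-107 was called as higher under all 4 of these rescalings and miR-16-5p under 0. In the miR-15/16 family, whose textbook target is BCL2, 1 of 6 members rose, miR-16-5p, also when adjusted over the list alone. MiR-15a-5p and miR-424-5p had changes of 0.27 and 0.13. In the miR-181 family, 1 of 3 rose, miR-181a-3p by 0.41, and 3 adjusted over the list alone. MiR-181a-5p and miR-181b-5p each changed by 0.35 without passing over all miRNAs. Under the same 4 rescalings, miR-23a-3p and miR-181a-3p were each called under 0 and miR-146a-5p under 1.

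The oncogenic cluster of miR-17 to miR-92a and its paralogs gave 0 calls among 14 tested members, also when adjusted over the list alone. MiR-20a-5p, miR-17-5p, miR-19b-3p and miR-92a-3p, its brightest members, had changes of 0.17, 0.18, 0.19 and -0.16. In the let-7 family, 1 of 9 members rose, let-7e-5p, also when adjusted over the list alone, while let-7a-5p, let-7f-5p, let-7d-5p and let-7g-5p had changes of -0.09, -0.05, -0.05 and 0.21. None of the 5 tested members of the miR-30 family and 0 of 3 of the miR-29 family passed, over all miRNAs or adjusted over the list alone. MiR-30e-5p and miR-29a-3p had changes of -0.11 and 0.05. MiR-221-3p and miR-222-3p, which repress the cell cycle inhibitor p27, had changes of 0.13 and 0.15. They were the tested members of their cluster, with 0 calls in either adjustment. Of the miRNAs encoded in the HOX clusters 1 was tested, miR-196a-5p, with a change of 0.21 and no call. Of 61 miRNAs of the imprinted 14q32 cluster 1 was tested, miR-494-3p, at -0.29 and not called. Many of these values that did not pass changed sign with the scaling, and others passed as lower. Under the median, miR-92a-3p (-0.36, adjusted p = 0.00813), let-7a-5p (-0.29, adjusted p = 0.0333), let-7f-5p (-0.25, adjusted p = 0.0333) and let-7d-5p (-0.25, adjusted p = 0.0456) were called as lower. MiR-92a-3p was also called as lower with the value table and after centring, miR-30c-5p after quantile normalization (-0.29, adjusted p = 0.0339) and miR-494-3p with the percentile over all miRNAs (-0.58, adjusted p = 0.0480).

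**Figure D4:**
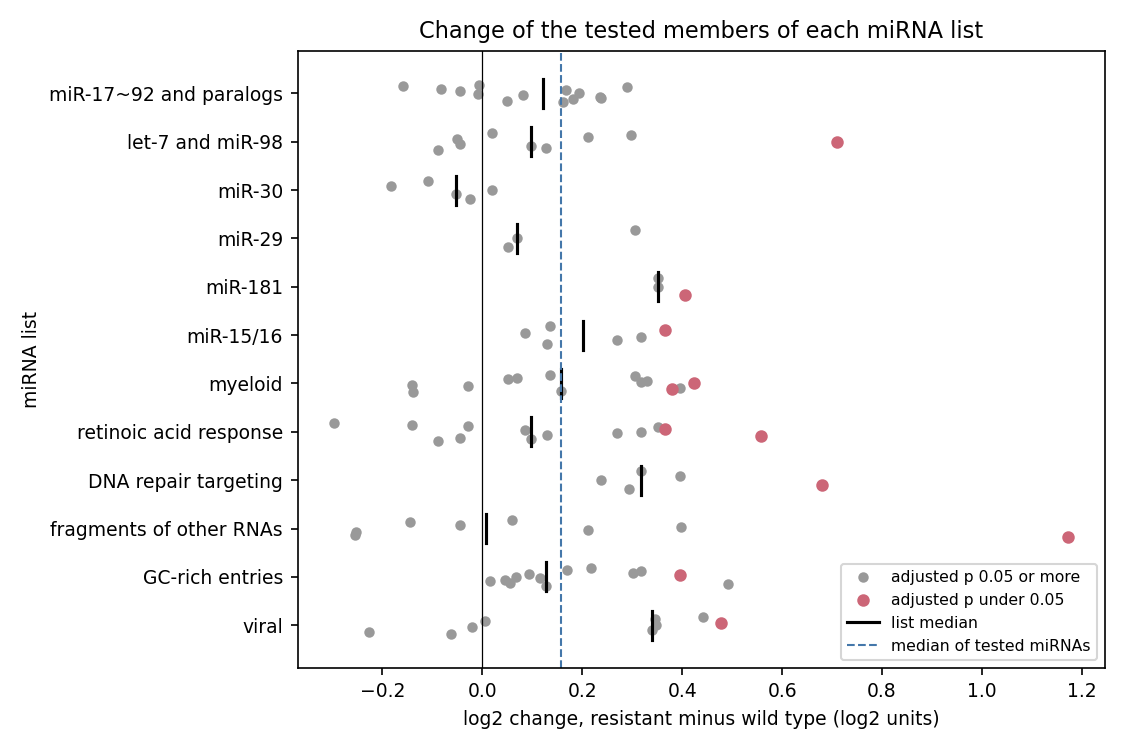
Log2 change, resistant minus wild type (x axis), of each tested member of the 12 miRNA lists with 3 or more tested members (y axis). Red points have an adjusted p under 0.05, the black bar is the median of the list, and the dashed line is the median of all tested miRNAs, 0.16. No list differed from the remaining miRNAs in the test of lists.

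Among miRNAs described as targeting DNA damage response genes, 1 of 5 tested members rose, miR-155-5p, and 3 did adjusted over the list alone. The values of the others named were 0.40 for miR-21-5p, 0.32 for miR-24-3p and 0.24 for miR-18a-5p. Over the 4 rescalings by the median, the quantile, the value table and the centring, miR-155-5p was called under 1. Of 17 p53-associated miRNAs 1 was tested and rose, miR-1246, also when adjusted over the list alone. Across the 12 lists with at least 3 tested members, 0 passed camera, which compares a list with the other miRNAs, and 1 had an unadjusted p under 0.05. That list was the miR-30 family (p = 0.0241, adjusted p = 0.289, and p = 0.258 with an estimated correlation). No list passed with an estimated correlation, where 0 had an unadjusted p under 0.05, or with fry, which asks whether the members move one way (3 lists with an unadjusted p under 0.05, smallest adjusted p = 0.123). Because camera compares with the other miRNAs, its direction was down for the miR-17 cluster, let-7, retinoic acid, miR-29, fragment and viral lists, whose median and mean changes were above 0.

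Markers of other cell types were scarce. The epithelial, erythroid and pluripotent stem cell lists and the miR-183 cluster had 0 members detected on any array. Of the mesenchymal and endothelial list, 2 members were tested. MiR-199a-3p rose by 0.42 (adjusted p = 0.0285) and miR-199b-5p had a change of 0.33, and both passed adjusted over the list alone. Of the lymphoid list 1 was tested, miR-155-5p, which rose in either adjustment. Of the liver and serum list 1 was tested, miR-483-5p, with a change of 0.04 and no call. Of entries that match fragments of other RNAs, 8 were tested and 1 rose, miR-1246, or 2 adjusted over the list alone. MiR-720, miR-1274b and miR-1274a, which match tRNA, had changes of 0.06, 0.21 and -0.25. Of 13 tested GC-rich entries, which can follow RNA input and array quality, 1 rose in either adjustment, miR-3665. MiR-638 and miR-1202 had changes of 0.22 and 0.13. All 13 had changes above 0 as scaled here, with a median of 0.13, where the median over all tested miRNAs was 0.16. Of 9 tested viral entries 1 rose in either adjustment, the herpes simplex virus entry hsv1-miR-H18 by 0.48, while hsv1-miR-H1-3p and ebv-miR-BART12 had changes of -0.02 and -0.06. MiR-199a-3p, miR-3665 and hsv1-miR-H18 were called under 0 of the 4 rescalings by the median, the quantile, the value table and the centring.

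The amount and concentration of miRNA signal were compared by 3 quantities, none of which passed. Wild-type arrays detected 164.3 ± 17.5 miRNAs and resistant arrays 175.0 ± 23.9 (exact two-sided permutation p = 0.514). The log2 total signal before scaling was 16.42 ± 0.27 and 16.41 ± 0.41 (exact permutation p = 0.971). The 10 brightest miRNAs held 71.0% ± 2.40 and 70.1% ± 1.26 of it (exact permutation p = 0.514), and miR-720 alone held 34.6% ± 3.17 and 32.9% ± 1.83. Adjusted over the 3 comparisons, the p-values were 0.771, 0.971 and 0.771, and the smallest that 4 against 4 arrays allow is 0.0286. These 3 differences are smaller than the spread between arrays of a group. The spike-in RNAs added at labelling had a log2 signal of 10.87 ± 0.19 on wild-type and 10.43 ± 0.22 on resistant arrays (exact permutation p = 0.0571). Relative to them the log2 total signal was 5.55 ± 0.19 on wild-type and 5.98 ± 0.48 on resistant arrays (exact permutation p = 0.143). Those added at hybridisation had 12.44 ± 0.25 and 11.87 ± 0.02 (exact permutation p = 0.0286).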

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

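In the tests below, those of scaling, of residual background, of probes, of RNA degradation and of the changes in row 2 were chosen after the results they measure were seen, and those of slide columns and of the spread in the rows before.

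Every miRNA called between the groups, 25 of 163, was higher in resistant arrays. Of 35 splits of the 8 arrays into 4 and 4, 1, the real one, gave as many, and the highest other split gave 3. A share of 1 in 35 is the smallest this test can give, and it was run only with the scaling used here. It argues against chance for the count under that scaling but cannot exclude it. Residual background in dim signals stays open: the mean change of the called miRNAs, 0.58 (SE 0.10), was 0.64 (SE 0.14) after the negative-control signal was subtracted, but 0.38 (SE 0.05) after normexp without an offset, and each of these corrections left 11 calls, all higher. The scaling stays open: without it the array medians differed between groups by 0.0356 with a standard error of 0.26, so a real shift of 0.16 could not be told from none. A trend across slide columns also stays open, since the called miRNAs differed between neighbouring columns of one group by 0.10 (SE 0.11) where 0.27 would be needed, with values from -0.04 to 0.43, and a step between the columns of the 2 groups cannot be told apart from the groups.

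MiR-1246, miR-324-5p and miR-124-3p were higher in resistant arrays under every scaling. A single deviating probe is argued against. Apart from the brightest probe, which carries the sum, miR-324-5p and miR-124-3p each had 1 bright probe, and both of these (100%) were higher, by 1.27 (SE 0.21) and 0.83 (SE 0.12). MiR-1246 had 1 further probe, which held 4.73% of the signal of its brightest and was higher by 0.82 (SE 0.15). For a linear trend across slide columns, the 3 miRNAs differed by 0.14 per column within groups (SE 0.12), where 0.55 would be needed. This mean argues against such a trend, but only in part. The values ran from -0.03 to 0.49, and the highest, of the wild-type arrays of row 2, came near the needed one. For miR-1246, a like rise of all fragment entries is argued against. The other 7 tested had a median change of -0.0438 (SD 0.24), from -0.25 for miR-1260b to 0.40 for miR-1275. Several of them match tRNA, so they cannot speak on breakdown of the U2 RNA that miR-1246 matches. Spike-ins added at hybridisation do not come from the cells, yet they separated fully between the groups. Their log2 signal was 12.44 ± 0.25 on wild-type and 11.87 ± 0.02 on resistant arrays. The arrays thus differed in a way not supplied by the cells, though with lower signal on the resistant arrays. A step between slide columns and the radiation history of the cells, which the design gives as the biological difference, both stay open. The change may therefore be biological only as a hypothesis.

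Row 1 of the slide gave 31 calls and row 2 gave 0. Different changes in the rows stay open. The 31 miRNAs called in row 1 had a mean change of 0.40 (SE 0.16) in row 2, each counted in its direction in row 1, against 0.64 in row 1. That is too imprecise to tell an equal change from a smaller one. The value of row 1 is also raised by the choice of these miRNAs there, so a smaller value in row 2 could arise with equal changes. Over all 163 tested miRNAs the changes in the 2 rows correlated at 0.745, and 0 interactions of group and row passed limma's test (4 at an unadjusted p under 0.05, smallest adjusted p = 0.998). A larger spread is in line with the residual standard deviation, which was 1.74 times larger in row 2 (0.20 against 0.11). No biological explanation was tested, since the rows hold both groups alike.

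Of 142 groups of 4 arrays examined, 14 had 1 array far from the others, where chance gives about 1 in 20. The values given for them are the gap to the nearest array as a share of the whole range. On wild-type replicate 3 they were the share of the 10 brightest miRNAs (0.841, at 74.6% against 69.3% to 70.1%), miR-92a-3p (0.849) and miR-23a-3p (0.850). On wild-type replicate 1 they were miR-142-3p (0.841), miR-221-3p (0.883), miR-222-3p (0.985) and miR-199b-5p (0.832). For miR-222-3p the other arrays lay at or next to the floor. On wild-type replicate 4 they were miR-362-5p (1) and miR-99a-5p (1), where the other 3 arrays lay at the floor. On resistant replicate 4 they were miR-128-3p (0.856), miR-720 (0.935) and miR-1274b (0.932). On resistant replicate 3 it was miR-638 (0.899), and on resistant replicate 1 ebv-miR-BART12 (0.899).

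Each of 10 families of control probes had a lower mean on the resistant arrays, with log2 changes from -0.11 to -0.71, and 4 were lower on all 4 resistant arrays than on any wild-type array (exact two-sided permutation p = 0.0286 each, the smallest possible, and 0.0714 after adjustment over the 10). Their log2 changes were -0.49 for dmr_285, -0.42 for dmr_3 and -0.71 for dmr_6, which are among the spike-ins of labelling and hybridisation, and -0.34 for hur_1.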

How the results depend on the processing

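Centring on the median of the tested miRNAs, subtracting the negative controls, normexp without an offset and scaling to spike-ins were chosen after seeing the data. The 25 calls became 3 with the percentile over all miRNAs (33.3% higher), 30 with the median (43.3% higher), 10 after quantile normalization (60.0% higher), 15 with the value table (40% higher) and 14 after centring (57.1% higher). There were 2 calls with normexp, whose offset of 50 damps the changes of dim miRNAs, 11 without that offset, 9 with the total gene signal, 11 after subtracting the negative controls, 4 with spike-ins (100% higher), where the median change became 0.50, and 2 at a threshold of 2-fold. No scaling gave 0 and no filter gave 0 with limma (4 and 59 at an unadjusted p under 0.05). Without the filter 8 lists passed, where most of the 1347 miRNAs lie at the floor. In every other setting in which the lists were tested, 0 passed. The splits of the arrays say nothing on chance here, since any split gives at least the real count of 0 lists (35 of 35, highest other 3). Row 2 alone gave 0 calls, with 4 arrays in the fit. Both other floors, the other filters, the mean of log2 probe values, the trend with robust variance, the row block and row 1 alone kept the count within 1.5 times. The members were not always the same. With the row block all 25 were kept. Of the 26 calls with a floor at the 20th percentile, 18 were among the 25. The same held for 16 of the 24 calls with detection on at least 1 array. In row 1 alone it held for 20 of 31, of which 29 were higher and 2 lower. The cause of these differences was not tested, except for the rows. "Slide as a block" was not run, since there is 1 slide.

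With each replicate left out in turn, the count ranged from 4 to 41 and the share that was higher from 88.2% to 100% (lowest without wild-type replicate 3). MiR-1246, miR-124-3p, miR-324-5p and miR-324-3p were called in all 8 of these fits. MiR-1246 was higher in 30 of 30 settings, from 0.83 to 1.54, and called in 27. The ranges were wider relative to the change for miR-324-5p, from 0.29 to 1.91 and called in 24 of 29 settings. MiR-124-3p ran from 0.36 to 1.15 and was called in 25 of 30. Of the 25 called miRNAs, 22 were above 0 in every setting, and the 3 others fell to exactly 0 at the higher floor. Values of miRNAs that did not pass changed sign 126 times across settings, in none of which they passed. The replicate numbers do not pair the arrays: the deviations of same-numbered arrays correlated at -0.22, -0.04, -0.47 and -0.29, and each correlated better with another number. With the replicate block there were 7 calls. The difference in log2 total signal ranged from -0.17 to 0.14, and was 0.04 and 0.09 without wild-type replicates 1 and 4 and 0.14 and 0.06 without resistant replicates 2 and 4. The difference in the share of the 10 brightest ranged from -1.55 to 0.24 percentage points, above 0 without wild-type replicate 3. Neither difference passed its test in any of these. Few spots lie well above background, so changes of miRNAs near the floor are understated.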

Other observations

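Among the tests in this part, that of neighbouring genes was chosen before its result was seen, and the shuffling within 3 classes of signal and the test without the miR-17 cluster and its paralogs after it.

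Several miRNAs made from one transcript had like changes, by pairs chosen after their values were seen. Let-7e-5p and miR-125a-5p, which share a cluster, had changes of 0.71 and 0.56, although only the former passed the test (adjusted p = 0.0140 and 0.0534). In the cluster of miR-23a, miR-27a and miR-24, the values were 0.42, 0.33 and 0.32. In its paralog, miR-23b-3p and miR-27b-3p had -0.23 and -0.12, while miR-24-3p is made from both clusters. MiR-188-5p and miR-362-5p, neighbours on the X chromosome, had 0.54 and 0.44. Their neighbour miR-660-5p had 0.16, with all wild-type values at the floor, so that its change is understated. Let-7c-5p and miR-99a-5p, also neighbours, had unlike changes of 0.10 and 0.40.

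A hypothesis is that miRNAs encoded within 10 kb of each other changed together. Over 52 pairs of neighbours whose names carry different numbers, the mean absolute difference of log2 change was 0.178. After shuffling the changes it was 0.307 (one-sided permutation p = 0.00440, 10000 resamples). Such pairs still include members of one family, such as miR-15a-5p and miR-16-5p. They also include arms of one hairpin, such as miR-16-2-3p and miR-16-5p. Shuffling within 3 classes of signal gave a permutation p of 0.00140. Without the miR-17 cluster and its paralogs 19 pairs were left, with 0.188 against 0.311 (permutation p = 0.0235). Changes at the level of shared transcripts could give this, but likeness of sequence within families was not removed. Pairs also overlap within clusters and are not independent. Whether such a difference came with the irradiation or with the separate culture of the cells was not tested.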
